A study of Mus musculus with 4 samples.

How the data were processed

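RNA from 4 cultures of mouse erythroid cells was measured on the Affymetrix GeneChip Mouse Gene 1.0 ST, a single-colour array whose probes lie along the whole length of each transcript. The labels give 2 groups of 2 cultures, lettered A and B: differentiating MEL cells, an erythroleukemia line, and differentiating ES-EP cells, erythroid progenitors derived from embryonic stem cells. Per the labels' protocols, total RNA was purified on spin columns and labelled with biotin. The design text speaks of duplicate cultures and says nothing of when they were grown, so the p-values measure the spread between these cultures and cover no further source of variation.

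The deposited table holds log2 values made by RMA (robust multi-array average, which corrects background, quantile-normalizes the probes and summarises them per feature) in GeneSpring GX, per the labels and the submitters' processing notes. The log2 scale was read from the values, which have the range and replicate scatter that RMA gives. The software version, the filters, the probe annotation and which arrays were normalized together are not given in the sources used here. RMA pulls the distributions of the arrays together, so a change in the total amount of RNA per cell cannot be seen in such values. It also leaves a floor for dim features, and a fold against a group near that floor understates the change. The table has no detection calls, so a low value was not told from background.

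The table has 35557 features. Of these, 6613 carry consecutive low numbers, are absent from the annotation and are known from the design of this array as control features. They were left out of the tests, and 28944 features were tested. The gene names came from a platform annotation, brought up to date through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, in which 21698 features found their gene. A total of 21789 tested features had 1 gene symbol, 1621 had several and 5534 had none. No gene was named from a feature with several symbols. The 1 symbol features stood for 19938 genes, and the brightest feature over the 4 arrays represented a gene that had more than 1. The build of the array's coordinates is not given in the sources used here, so no coordinates are printed and the RefSeq table served only for names and for which genes neighbour each other.

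The groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the deposited values and Benjamini-Hochberg adjustment over the 28944 features. A feature was counted as higher or lower in MEL at an adjusted p under 0.05 and a log2 difference of at least 1. The fit had 2 residual degrees of freedom and 5.15 from the prior. An exact permutation test of 4 arrays has 3 splits and cannot give a two-sided p under 0.333, so significance rests on the variance shared across features. Standard errors are those of the moderated fit, and SDs are those of the 2 cultures of a group. With 2 arrays per group, the number of arrays limits the precision.

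A set of 31 gene lists on erythroid genes, other cell types, the cell cycle and pathways related to the culture conditions was fixed before the data were examined, as were the tests and the rule for named genes. Of the 701 genes on them, 618 had a feature of their own. The 30 lists with at least 3 measured genes were tested with camera in limma, with its preset correlation of 0.01 between genes and adjustment over the lists. Camera compares a list with the other genes. The list of adult globins was not tested, because its genes share features. In all 83 list genes, Trp53 among them, were not analysed here. Named genes are the 8 with the largest difference in each direction, the members of each list with the largest passing rise and fall (and 1 further member in the erythroid, progenitor and myeloid lists), and 11 genes chosen for what they do, whatever their result. Predicted genes without a descriptive name were passed over. Each list's median was also set against 10000 random lists of the same size, drawn from 40 bins of mean signal.

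The alternatives were quantile normalization of the deposited values, centring on array medians, a prior with an intensity trend or a robust one, 2 filters on dim features, features with 1 symbol only, the replicate letter as a block, a 1.5-fold criterion, treat against 1.5-fold, and each culture left out in turn. For the lists they were an estimated correlation, fry, and the mean of a gene's features. Cyclic loess between the arrays and the inclusion of the control features were added after the data were seen.

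The procedure was tested on simulated data made from the means and spreads of the 28944 features for the comparison of MEL with ES-EP, with 200 features changed. It recovered 98.0% of the features changed by 1.5-fold and 100.0% of those changed by 2, 4 or 8-fold, each size with 50 features, and called 9 unchanged features. Of 5 simulated lists of 20 genes shifted by 0.7 it called 5, and of 30 unshifted lists 0. All but 200 of the simulated features had no difference and all varied independently, while 56.5% of the real features passed. Camera sets a list against the other genes, so the simulated lists were easier to call than real ones. They do not show how the list test performs on these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.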

Results

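Gene expression was measured in cultures of leukemic and normal mouse erythroid progenitors that had been set to differentiate. MEL cells are an erythroleukemia line that can be induced to mature towards red cells. They were grown in medium with serum and puromycin and induced with estradiol for 48 hours. ES-EP cells are erythroid progenitors obtained from embryonic stem cells. They had been expanded with erythropoietin, insulin-like growth factor, the glucocorticoid dexamethasone and stem cell factor, and were differentiated for 24 hours in medium with erythropoietin, insulin and the glucocorticoid antagonist mifepristone. Each group had 2 cultures, with 1 array per culture. The cell line, inducer, medium and hours differed together, and undifferentiated cultures were not analysed here, so the comparison is of 2 differentiating culture systems and gives no change during differentiation.

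The MEL and ES-EP arrays differed far more from each other than the duplicates did. The 2 MEL arrays correlated with r = 0.997 across features and the 2 ES-EP arrays with r = 0.998, against 0.948 to 0.949 between the groups. Features are not independent replicates, and the correlations only describe the arrays. Between the MEL duplicates 61 of 28944 features were at least 2-fold apart, between the ES-EP duplicates 4, and between arrays of different groups 3348 to 3399. Array medians lay at 5.89 and 5.78 for MEL and 5.91 and 5.89 for ES-EP.

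A total of 1816 features were at least 2-fold higher in MEL than in ES-EP cells and 1495 were at least 2-fold lower (limma, adjusted p under 0.05). Counted as genes, 1472 of 19938 were higher and 982 were lower, and 50 and 37 of these differed by at least 16-fold. Without a fold criterion 56.5% of the features passed. Of these 33.8% were higher in MEL, a share that became 45.6% after quantile normalization and 51.9% after cyclic loess. Of all genes 21.8% passed as higher and 36.9% as lower on the values as deposited. The counts of higher and lower list members below are best read against these 2 shares. The median difference of MEL minus ES-EP over all genes was -0.14 on the log2 scale as deposited, -0.02 after quantile normalization, -0.07 after centring and 0.02 after cyclic loess. Small differences are therefore best read against that shift, and the medians of the 5 lists that passed are given below also relative to it. The shift depended on signal, with gene features of mid level slightly higher in MEL and dim ones lower, while control features were lower in MEL over most levels.

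**Figure D1:**
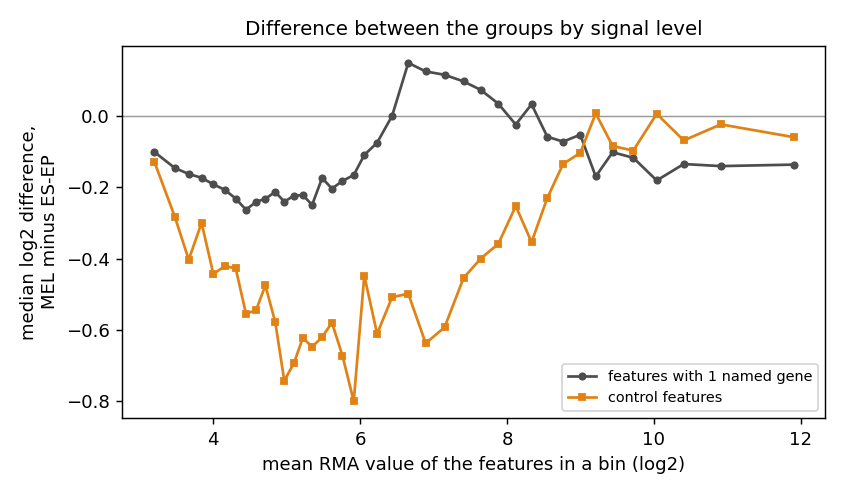
Median log2 difference of MEL minus ES-EP (vertical axis) against the mean RMA value in log2 of features in 40 bins of signal (horizontal axis), for features with 1 named gene (circles) and for control features (squares). The control features lie lower than the gene features at low and middle signal, with a median difference of -0.62 for those with a mean level of 5 to 7.

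Genes with little signal in ES-EP cells and strong signal in MEL cells led the list of higher genes. Gstm5, a glutathione transferase (feature 10495243), had a mean log2 value of 10.76 ± 0.03 in MEL and 3.98 ± 0.10 in ES-EP cells (SD, n = 2), a 109.9-fold difference (adjusted p = 7.03e-08). Tceal8 was 62.5-fold higher, the actin-bundling protein gene Pls3 55.5-fold, the lipoxygenase Alox5, which starts leukotriene synthesis, 45.8-fold, and the chemokine receptor Ccr2 44.97-fold. Adssl1, an adenylosuccinate synthase, was 43.2-fold higher, and Trap1a, which encodes a tumour rejection antigen, 36.0-fold. The feature named for Kcnma1, a potassium channel gene, was 53.7-fold higher, but a dimmer second feature of this gene differed by -0.54 on the log2 scale, so the 2 features disagree and it is not settled that the brighter one measures this gene. In these 8 genes the log2 differences ran from 5.17 to 6.78 with standard errors of 0.08 to 0.11, and ES-EP means of 3.51 to 5.06 lay near the low end of the arrays' range.

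Genes far lower in MEL than in ES-EP cells included a central protein of the red cell membrane. Slc4a1, the anion exchanger of red cells (feature 10391649), had a mean of 7.04 ± 0.08 in MEL and 12.48 ± 0.04 in ES-EP cells (SD, n = 2), 43.4-fold lower in MEL (adjusted p = 7.05e-08). The guanine deaminase gene Gda was 69.3-fold lower in MEL. Grb10, an imprinted gene for an adaptor that restrains insulin receptor signalling, was 54.5-fold lower, and the mitochondrial protein gene Fastkd2 was 49.6-fold lower. Il1rl2, a receptor of the interleukin family, was 48.8-fold lower, the phosphoribosyl pyrophosphate synthetase Prps2 44.4-fold and Ugt8a, a ceramide galactosyltransferase, 43.7-fold. Lmbr1 was 39.5-fold lower, and its second, dimmer feature was also lower, by -1.63 on the log2 scale.

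Gata1, Klf1, Tal1, Epor, Spi1 and Myb differed by less than 2-fold between the systems, while Fli1 and Kit differed by more. Gata1, the master transcription factor of red cells, was slightly higher in MEL (0.46 ± 0.08 on the log2 scale, SE, n = 2 per group, adjusted p = 0.00251), as was the erythropoietin receptor gene Epor (0.42 ± 0.08, adjusted p = 0.00413). Klf1, which activates the adult beta globin gene, was lower (-0.81 ± 0.08), and so was Tal1 (-0.55 ± 0.08). Spi1, a myeloid transcription factor known for its activation in erythroleukemia, was at 8.61 ± 0.07 in MEL and 8.73 ± 0.03 in ES-EP cells (SD, n = 2), a difference of -0.12 with a 95% interval of -0.32 to 0.07 that did not pass (adjusted p = 0.243). Fli1, an ETS factor of megakaryocytes, was 18.7-fold higher in MEL, at 9.28 ± 0.07 against 5.06 ± 0.11 (SD, n = 2). Kit, the receptor of stem cell factor, was 7.40-fold lower. Myb (0.20, adjusted p = 0.0781) and the glucocorticoid receptor gene Nr3c1 (0.16, adjusted p = 0.138) did not pass, though both passed after cyclic loess. Myb also passed with features under the median left out (limma, adjusted p = 0.0485). The estrogen receptor gene Esr1 was dim in both groups, at 5.63 and 5.32, and its difference of 0.31 (adjusted p = 0.0168) no longer passed without ES-EP culture A or B (adjusted p = 0.0924 and 0.0915).

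**Figure D2:**
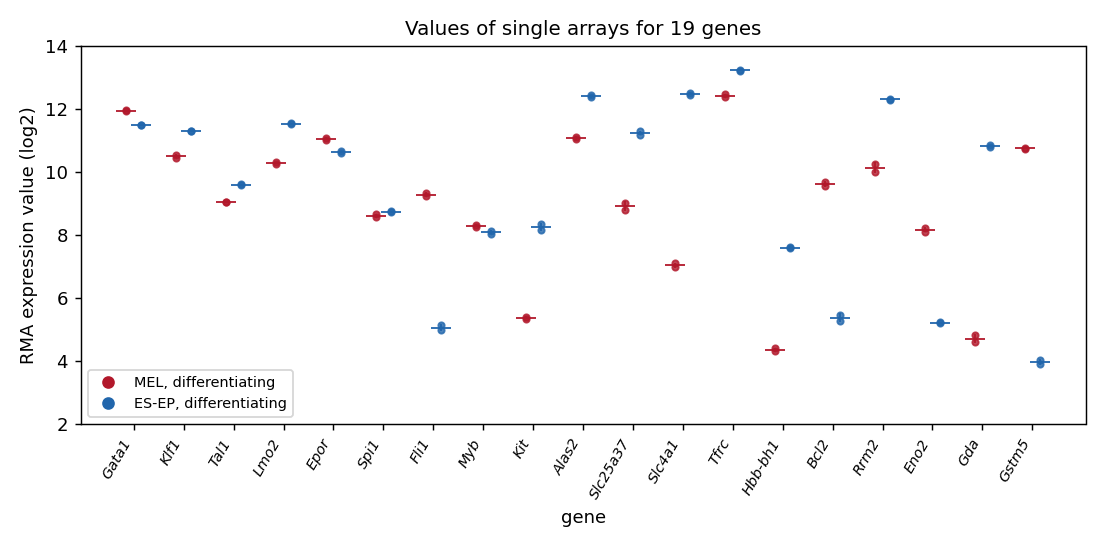
RMA expression values in log2 (vertical axis) of 19 named genes (horizontal axis) on single arrays, with MEL in red and ES-EP in blue. Points are the 2 cultures of a group, the dash is their mean and the vertical line ± 1 SD. Gata1, Epor, Spi1 and Myb lie close together in both groups, while Fli1, Bcl2 and Gstm5 lie high in MEL only, and Slc4a1 and Gda high in ES-EP only.

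Genes of heme synthesis and of late red cell maturation were lower in MEL as groups. Of 14 measured heme genes, 13 were lower and 1 was higher, with the same counts when adjusted over the list alone, and the median difference of -0.67 was -0.53 relative to that of all genes (camera, adjusted p = 0.00406, and 0.612 with an estimated correlation). Slc25a37, the mitochondrial iron importer, was 5.00-fold lower (-2.32 ± 0.10, SE, n = 2 per group), and Alas2, which catalyses the first step of heme synthesis in red cells, 2.51-fold lower at a still high 11.08. Abcb6 was the higher member (0.25, adjusted p = 0.0308), and its call was lost without ES-EP culture A or B or MEL culture B (adjusted p = 0.161, 0.1501 and 0.0658). In the late maturation list 22 of 29 genes were lower and 3 higher (24 and 4 adjusted over the list alone), with a median of -0.74, -0.60 relative to all genes (camera, adjusted p = 0.00102, and 0.612 with an estimated correlation). Bpgm, the enzyme that makes bisphosphoglycerate, was 4.89-fold lower, the erythroid claudin Cldn13 was 4.28-fold lower, and Trim10, a gene of terminal erythroid differentiation, went the other way and was 7.51-fold higher.

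The other erythroid lists did not pass as groups on the values as deposited, and most held large differences in both directions. Of 21 membrane and skeleton genes 13 were lower and 4 higher (16 and 4 adjusted over the list alone, camera adjusted p = 0.211), and this list passed after cyclic loess (adjusted p = 0.0405). In contrast to Slc4a1, the water channel Aqp1 was 4.96-fold higher in MEL, and so was the tropomodulin gene Tmod1 by 6.495-fold, though a second feature of Tmod1 differed by only 0.02. Among 18 erythroid transcription factors 10 were lower and 4 higher, also over the list alone (camera, adjusted p = 0.285). E2f2, a cell cycle factor of erythroblasts, was 4.06-fold lower and Lmo2 2.36-fold lower, while Cbfa2t3 was 2.05-fold higher on its brighter feature and differed by 0.01 on the other. The 16 iron genes had 3 higher and 6 lower members, also over the list alone (camera, adjusted p = 0.914), and their median changed sign after quantile normalization, with 6 higher and 6 lower. After cyclic loess the counts were 6 and 5. They included Fbxl5, an iron sensor, at 2.03-fold higher, the heme-degrading Hmox1 at 3.42-fold lower, and the transferrin receptor Tfrc at 1.75-fold lower. All 3 measured embryonic globin genes were lower in MEL, also over the list alone, and the list just missed the threshold (camera, adjusted p = 0.0502). It passed after quantile normalization (camera, adjusted p = 0.0293) and after cyclic loess (0.0169). Its median of -1.09 was -1.09 without ES-EP culture A and -1.10 without culture B. Hbb-bh1 was at 4.35 ± 0.07 in MEL and 7.60 ± 0.04 in ES-EP cells (SD, n = 2), 9.51-fold lower, and Hba-x was 2.14-fold lower. Hbb-y was dim in both groups, at 4.26 in MEL and 5.07 in ES-EP cells.

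**Figure D3:**
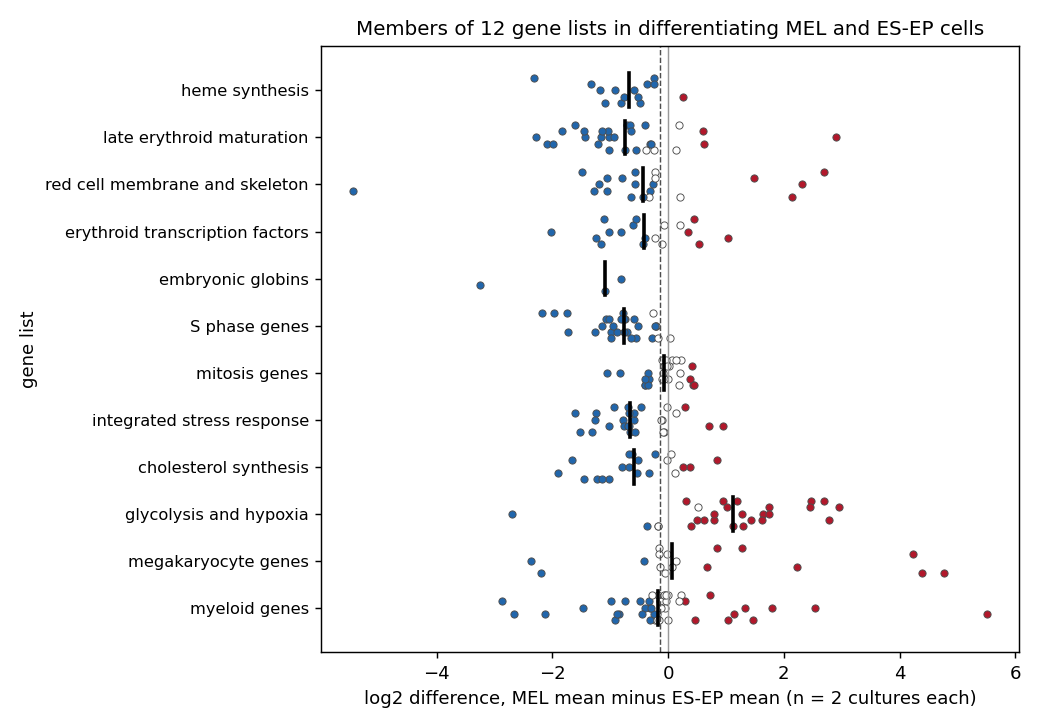
Log2 difference of MEL minus ES-EP (horizontal axis) for each measured gene of 12 gene lists (vertical axis), each difference from 2 cultures per group. Filled points passed at adjusted p under 0.05, red for higher and blue for lower, open points did not, black bars are list medians and the dashed line is the median of all genes. The list medians run from -1.09 for embryonic globins to 1.12 for glycolysis and hypoxia.

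Genes of S phase were lower in MEL, while those of mitosis were balanced. Of 29 S phase genes 0 were higher and 24 were lower (0 and 27 adjusted over the list alone), with a median of -0.77, -0.63 relative to all genes (camera, adjusted p = 2.63e-06, and 0.752 with an estimated correlation). Rrm2, the regulated subunit of ribonucleotide reductase, was at 12.31 ± 0.02 in ES-EP and 10.14 ± 0.17 in MEL cells (SD, n = 2), 4.53-fold lower in MEL. Of 27 mitosis genes 4 were higher and 8 lower, also over the list alone (camera, adjusted p = 0.914), and their median of -0.06 turned positive under all 3 other scalings. The counts became 9 higher and 6 lower after quantile normalization, 4 and 5 after centring, and 8 and 7 after cyclic loess. The mitotic kinase Plk1 was 1.36-fold higher and Birc5, a subunit of the chromosomal passenger complex, 2.08-fold lower. Among 18 cell cycle inhibitors and D cyclins 2 were higher and 11 lower, also over the list alone (camera, adjusted p = 0.193), with the inhibitor Cdkn2d 2.497-fold higher and its relative Cdkn2b 4.63-fold lower.

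Glycolytic and hypoxia-responsive genes formed the strongest group difference and were higher in MEL. Of 27 measured genes 22 were higher and 2 lower, also over the list alone, with a median of 1.12, 1.26 relative to all genes (camera, adjusted p = 1.81e-09, and 0.541 with an estimated correlation). Eno2, an enolase, was at 8.17 ± 0.08 in MEL and 5.22 ± 0.01 in ES-EP cells (SD, n = 2), 7.72-fold higher. Egln3, a prolyl hydroxylase that is itself induced by hypoxia, was the main exception, at 6.46-fold lower. Genes of the integrated stress response were lower, 18 of 27 against 3 higher, also over the list alone, with a median of -0.66, -0.52 relative to all genes (camera, adjusted p = 0.0199, and 0.914 with an estimated correlation). Their call was lost without MEL culture A (adjusted p = 0.0894). Dnajb9, a chaperone gene of the endoplasmic reticulum, was 3.05-fold lower, and the serine synthesis gene Psat1 was 1.94-fold higher. Of 20 cholesterol synthesis genes 14 were lower and 3 higher, also over the list alone. That list missed the threshold (camera, adjusted p = 0.0561) and passed after quantile normalization (0.0261) and cyclic loess (0.0131). Its median of -0.58 was -0.59 without ES-EP culture A and -0.58 without culture B. Hsd17b7 was 3.72-fold lower and Nsdhl 1.80-fold higher.

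Markers of other blood cell types split in both directions, and none of these lists passed. Of 17 megakaryocyte genes 7 were higher and 3 lower, also over the list alone (camera, adjusted p = 0.0863). The tetraspanin gene Cd9 was 27.2-fold higher in MEL, as was Fli1 above, while the integrin gene Itgb3 was 5.15-fold lower. The megakaryocyte list's median of 0.06 became -0.03 without ES-EP culture A and 0.14 without culture B. Among 44 myeloid genes 10 were higher and 17 lower (10 and 19 adjusted over the list alone, camera adjusted p = 0.914). Their median of -0.17 turned positive after quantile normalization, with 12 higher and 12 lower, and after cyclic loess, with 12 and 11. Alox5 stood beside Csf2rb2, a cytokine receptor gene that was 7.28-fold lower, and the Fc receptor gene Fcgr2b, 6.33-fold lower. Of 25 stem and progenitor genes 6 were higher and 9 lower (7 and 9 adjusted over the list alone, camera adjusted p = 0.894). Their median of -0.09 turned positive after quantile normalization, with 7 higher and 6 lower, and after cyclic loess, with 9 and 6. Cd48 was 15.6-fold and Meis1 7.86-fold higher, against the lower Kit. Of 14 mast cell and basophil genes 2 were higher and 8 lower, also over the list alone (camera, adjusted p = 0.261). Ms4a2, a chain of the IgE receptor, was 11.5-fold lower, and the monoamine transporter Slc18a2 4.99-fold higher.

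Lists for cells outside these lineages had median levels of 4.84 to 5.79 in MEL and 4.92 to 5.50 in ES-EP cells, with some brighter members such as Btk, at 9.99 and 9.04. Lymphoid genes had 1 higher and 10 lower members of 23, also over the list alone (camera, adjusted p = 0.449), with Btk 1.92-fold higher and Vpreb1 1.51-fold lower. Pluripotency genes had 3 higher and 9 lower of 17 (3 and 10 over the list alone, camera adjusted p = 0.696), with Dnmt3b 1.92-fold higher and Esrrb 1.74-fold lower. Endothelial genes had 4 higher and 3 lower of 15 (4 and 2 over the list alone, camera adjusted p = 0.840), with the receptor gene Tek 2.78-fold higher and Eng 2.44-fold lower. Stromal genes had 1 higher and 6 lower of 15, also over the list alone (camera, adjusted p = 0.571), with Pdgfrb 1.74-fold higher and Tagln 1.36-fold lower. The list medians, -0.16 to -0.33, were close to those of random lists of the same signal, -0.13 to -0.19, and the endothelial median turned positive after cyclic loess. The counts of these lists depended on the scaling. After cyclic loess the lymphoid list had 1 higher and 5 lower genes, the pluripotency list 4 and 5, the endothelial list 5 and 1, and the stromal list 1 and 2.

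Signalling lists tied to the culture conditions did not pass either. Of 20 genes of erythropoietin and STAT5 signalling 9 were higher and 8 lower, also over the list alone (camera, adjusted p = 0.846). The survival gene Bcl2 was 18.98-fold higher in MEL, at 9.62 ± 0.09 against 5.37 ± 0.14 (SD, n = 2), and the cytokine Osm 7.52-fold lower. The list's median was 0.14 and its mean -0.23, so the direction of this group depends on the summary. At least 2-fold, 2 of its genes were higher and 7 lower, so its larger differences were mostly downward. Among the lower ones Bcl2l1, picked after its value was seen, was 5.44-fold lower. Glucocorticoid-responsive genes had 4 higher and 9 lower of 17 (5 and 9 over the list alone, camera adjusted p = 0.810), with Klf9 5.40-fold lower and Errfi1 2.68-fold higher, and the counts became 7 and 8 after cyclic loess. Estrogen-responsive genes had 5 higher and 3 lower of 13, also over the list alone (camera, adjusted p = 0.261), with Igfbp4 7.71-fold higher and the progesterone receptor gene Pgr 1.47-fold lower. Their mean was 0.39 and their median -0.07, which turned positive after quantile normalization and cyclic loess. Of 26 p53 target genes 6 were higher and 13 lower, also over the list alone (camera, adjusted p = 0.914), with Pmaip1 4.89-fold higher and Psrc1 3.57-fold lower. Interferon response genes had 10 higher and 4 lower of 25 (10 and 5 over the list alone, camera adjusted p = 0.103). Ifitm3 was 25.5-fold higher and Ifit1 2.17-fold lower. The median of this list, 0.09, was 0.07 without ES-EP culture A and 0.09 without culture B. Antigen presentation genes had 8 higher and 3 lower of 12, also over the list alone (camera, adjusted p = 0.0863), with the immunoproteasome gene Psmb8 5.48-fold higher and Psmb10 1.74-fold lower.

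Among the remaining lists, 24 imprinted genes had 3 higher and 12 lower members, also over the list alone (camera, adjusted p = 0.123), with Grb10 the lowest and Phlda2 1.90-fold higher, and the counts became 5 and 8 after cyclic loess. The median of this list, -0.23, was -0.24 without ES-EP culture A and -0.25 without culture B. Of 53 ribosomal protein genes 5 were higher and 17 lower (4 and 17 over the list alone, camera adjusted p = 0.865), and their median of -0.09 turned positive after cyclic loess, with 12 higher and 12 lower. Rpl22 was 2.57-fold higher and Rpl12 2.10-fold lower. Of 7 linker histone genes 1 was higher and 3 were lower, also over the list alone (camera, adjusted p = 0.914), with H1f6 1.81-fold higher and H1f5 1.59-fold lower, and their median also turned positive after cyclic loess, with 2 higher and 2 lower. Among 6 sex chromosome genes 2 were higher and 2 lower, also over the list alone (camera, adjusted p = 0.551), and their median of -0.02 turned positive under all 3 other scalings, with 3 higher and 1 lower after quantile normalization and 2 and 1 after the others. The Y-linked Kdm5d was 10.97-fold higher in MEL, and Xist was dim in both groups, at 3.78 and 4.26. The other 4 measured Y-linked genes of the list are given after their values were seen. Eif2s3y was at 10.30 in MEL and 10.23 in ES-EP cells (adjusted p = 0.518) and Uty at 9.65 and 8.73, while Usp9y was at 3.63 and 3.94 and Zfy1 at 3.42 and 3.53, near the floor in both groups.

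Of the 30 lists, 5 passed with the preset correlation and 0 with a correlation estimated for each list in camera, where 1 list had an unadjusted p under 0.05. Fry, which asks only whether the genes of a list move one way, passed 19. The test's direction, relative to all genes, was upward for the mitosis, progenitor, endothelial, estrogen and sex chromosome lists, whose medians were below 0. The progenitor and mitosis means were below 0 as well, at -0.01 and -0.08, and the other means above it.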

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

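The control features of the array, which were left out of the main tests, stand out because they differed between the groups. Their median difference of MEL minus ES-EP was -0.38 on the log2 scale over 6613 features. Of these, 76.7% were lower in MEL, 1223 at least 2-fold lower and 60 at least 2-fold higher. The difference was -0.62 in the 2237 features with a mean level of 5 to 7 and -0.04 in the 856 with a level of 9 or more.

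An offset between the arrays that acts on every dim feature is argued against, mainly at middle levels, by the gene features of the same signal. Relative to these, the control features were still lower by a median of -0.26. The same measure was -0.11 between the MEL duplicates and -0.05 between the ES-EP duplicates. By mean level it was -0.50 at 5 to 7 and -0.41 at 7 to 9, but -0.17 under 5 and 0.10 at 9 or more. Under 5 it was close to the difference of the MEL duplicates, so the argument is weak for the dimmest features. Genomic DNA or unannotated transcription read by the ES-EP arrays would also raise features with no named gene. Their difference relative to gene features was -0.06, 22.7% of that of the control features, and 13.7% to 45.9% once the duplicates' differences are allowed for. That range is too wide to decide, so this source cannot be told apart from others for these features. The kinds of control feature were not separated here. Which arrays were normalized together is not given in the sources used here, and no biological explanation other than unannotated transcription was tested.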

How the results depend on the processing

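Cyclic loess and the inclusion of the control features were chosen after the data were seen, and the other alternatives before. The counts of 1816 higher and 1495 lower features stayed within 1.5 times under every alternative but 2. A 1.5-fold criterion gave 3193 and 4271 features, since it admits smaller differences. With the control features included 2631 were lower, since these features themselves lay lower in MEL. Leaving out each culture in turn, with the lone array assumed to vary like the pair of the other group, gave 1733 to 1935 higher and 1402 to 1593 lower features. The letters A and B are not stated to pair the cultures, and the differences between duplicates correlated with r = 0.11 across features. With the letter as a replicate block the counts were 1816 and 1495, with 5 lists. In the main fit all 3311 features with a log2 difference of at least 1 passed the adjusted p. The block and the 2 other priors leave the log2 differences unchanged, so their feature counts could only have fallen. The equal counts therefore say little about pairing or about the prior. The 5 lists that passed became 4 to 10 without a culture, 8 after cyclic loess, 19 with fry and 0 with an estimated correlation, a setting that called 5 of 5 simulated shifted lists of independent genes. For glycolysis and hypoxia the estimated correlation was -0.04, below the preset 0.01. This argues against correlation among its genes as the reason why that list lost its call. For the other lists that passed it was 0.06 to 0.39. With an estimated correlation camera takes its p from the 2 residual degrees of freedom of the fit, and with the preset one from far more. Few lists can pass on 2 degrees of freedom, so a call lost there does not tell whether a list is shifted. Without a culture the lone array's group has no spread of its own, so list calls gained or lost there are weak evidence. The causes of the other changes between these tests were not tested further. The list of erythropoietin and STAT5 signalling, not called by camera, turned from upward to downward with fry (adjusted p = 0.00947, median 0.143), and the cause was not tested. Over all alternatives the named genes kept direction and side of the threshold in 1277 of their comparisons, lost a call in 24, of which 18 were under treat against 1.5-fold, and gained one in 3. Signal over background limits the dim genes, whose folds are understated.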

Other observations

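The test of the S phase genes against random lists of the same signal and their comparison with the mitosis genes were chosen after the result was seen. The gene groups in the next 2 paragraphs, the adult globin features and the genes outside the rule for named genes were picked after some of their values had been seen.

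Lin28b, an RNA-binding protein gene of fetal blood progenitors, had strong signal in ES-EP cells and little in MEL cells, at 8.13 against 3.86 on the log2 scale. With the embryonic globin Hbb-bh1 also lower in MEL, a hypothesis was that a fetal programme linked to Lin28b is present in the ES-EP cultures. It was tested on genes associated with that programme that had not been looked at before, 6 in all, of which 4 were measured. Igf2bp1 (-2.75 ± 0.09, SE, n = 2 per group) and Igf2bp3 (-2.68 ± 0.10) were much lower in MEL, Hmga2 was lower (-0.94 ± 0.12), and Arid3a was slightly higher (0.37 ± 0.08). Their median of -1.81 lay at percentile 0.1 of 10000 random lists of the same signal, as the hypothesis predicts for these 4 genes. The random lists hold genes drawn independently, while genes of 1 programme may vary together, so the percentile may overstate the evidence. The origin of the cells, the hours and the medium differ with the group, so the data do not say which of them goes with it. Features shared by the copies of the adult alpha globin genes were near the top of the arrays' range in both groups and lower in MEL by -0.53 and -0.28, and those shared by the adult beta globin copies by -0.38 and -0.33. Saturation, which compresses differences between such bright features, was not measured here, so the sizes of these 4 differences are not firm.

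Several of the genes with the largest rise in MEL are known from germ cells or tumours, namely Trap1a (5.17), Rnf17 (4.88) and Xlr (4.17, all log2 differences). A wider expression of germ line genes in MEL was tested on 27 further measured germ line genes. Their median difference was -0.14, at percentile 61.1 of random lists of the same signal, which argues against a wide rise. Among them Tdrd9 (2.52) and Brdt (2.24) were at least 2-fold higher and Tex15 (-1.39) was at least 2-fold lower.

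A total of 87 genes differed by at least 16-fold, 50 higher and 37 lower in MEL. Gain or loss of chromosome segments in 1 line would carry neighbouring genes along. The neighbours of these genes differed in the same direction by a median of 0.17, above the upper end, 0.09, of the central 95% of 10000 random sets (one-sided permutation p = 2e-04), and 3 of the genes had a 2-fold difference in the same direction on both sides. The neighbours thus moved more than chance gives but by little, and a part played by such segments cannot be told apart from shared regulation. Sequence differences between the lines under the probes could give a false difference on 1 feature. Of the 8 genes with a second feature, 7 showed at least a 2-fold difference in the same direction on it (87.5%, exact binomial 95% interval 47.4% to 99.7%). Kcnma1 did not. Whether the 2 features of a gene share probe sequence was not checked, and features that do would agree in either case. The interval is wide and the other 79 genes have no second feature, so this stays open for all 87.

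The S phase genes had a median of -0.77 and the mitosis genes of -0.06, a difference of -0.71. No p is given for it, since the genes within each list vary together, and the S phase list itself did not pass with an estimated correlation (adjusted p = 0.752). A level-dependent offset between the arrays is argued against, since the median of the S phase genes lay below the 2.5th percentile of random lists of the same signal, -0.35. A smaller share of cells in S phase in the MEL cultures would also lower the core histone genes made with DNA replication. The 22 measured core histone genes were picked by symbol, and whether each is made with replication was not checked. Their median was -0.17 (bootstrap 95% interval -0.58 to 0.14), with 11 lower and 6 higher. Single differences ran from -1.09 for H2ac4 to 2.37 for H2bc21. The bootstrap takes the genes as independent, so its interval may be too narrow. The histone genes thus do not decide. A lower share of S phase cells cannot be told apart from lower expression of the S phase genes within a cell. The differences in hours, medium and cell line stay untested.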
